A study of Mus musculus with 28 samples.

How the data were processed

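RNA was prepared from cultured tumour cells with an RNeasy kit and made into libraries with an Illumina TruSeq RNA kit from total RNA, per the labels' protocols. Reads were aligned with STAR 2.5.1 to mm10 (GRCm38) and counted per gene with featureCounts, per the submitters' processing notes; the featureCounts version, the strand setting and the gene annotation are not given in the sources used here. The deposited values are raw counts per gene, one file per library with 24623 genes, per the file headers, and a column with the length of each gene. Each of the 28 libraries was mapped to its sample by the name the labels give it, and the 14 groups of 2 libraries were taken from line, genotype and treatment labels. Library totals ran from 8724714 to 22024231 counts, and genes with a count from 12590 to 15678. The ribosomal RNA precursor Rn45s took 0.338 to 14.7% of a library's counts (median 1.61%), with 14.7% in wild-type 3077c4 replicate 1. No 2 libraries were identical. Protein levels, histone marks and any other assay of the wider study were not analysed here.

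Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the design, TMM scaling, and quasi-likelihood F-tests with Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. In each line, 1 fit held all libraries of the line with 1 mean per group, and the mean of the 2 clones or the Tgf-b group was compared with the wild type; the 2 clones were also compared with each other. Effects over both lines were tested after summing the 2 libraries of each clone or wild type, with the line as a covariate, since clones and not libraries are the units. Tgf-b over both lines used single libraries with the line as covariate. Wild types of Panc02 and 3077c4 were compared with those of 6694c2 and 6419c5 as 1 sum per line. Differences of an effect between lines were tested as interactions. Groups, comparisons, main tests and the alternatives were written down before the data were examined, except those named as added. Standard errors of log2 changes were computed from the F statistics. Changes of simulated size were put into simulated counts of the same shape to test the scripts: at 4-fold, the share recovered was 71.2% for the Kdm2a-labelled clones of 6694c2, 92.4% for those of 6419c5, 86.2% for the Nsd clones of Panc02, 86.2% for those of 3077c4, 74.2% and 71.9% for Tgf-b in 6694c2 and 6419c5, 89.1% for Tgf-b over both lines, 0% and 71.4% for Kdm2a-labelled and Nsd clones by clone, and 0%, 56.2% and 11.1% for the 3 interactions. Unchanged genes made up 21.4% of the simulated calls for the Nsd interaction, 15.1% between the Panc02 clones, 12.3% for Nsd clones by clone, 11.7% for those of Panc02, 11.4% for the Kdm2a-labelled clones of 6419c5 and 0 to 8.77% in the other comparisons with calls, where 5% is nominal. Each comparison had a single simulated data set, in which only a small share of the genes changed. Real data may hold far more changed genes, so none of these shares carries over to the real calls.

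A gene without a count in 1 of the groups has no ratio, so its difference is given as a lower bound against a floor of 3 counts over that group. With 1 to 3 counts, the ratio is given with a counting interval, which covers counting error only. The fitted log2 change of such genes is no bound. Genes were named by a rule: in every comparison Kdm2a, Nsd1, Nsd2 and the panel Cdh1, Epcam, Vim, Fn1, Zeb1 and Snai1; then, among called genes with a mean log2 CPM of at least 2, a curated symbol and no overlap in CPM between arm and control within each line, the 6 largest rises and 6 largest falls in comparisons over lines and the 4 and 4 largest in each line; then the 2 members with the largest change in each list called by camera. Of the genes this rule names, 4 are not reported here. Chromosome positions are those of RefSeq on GRCm38.p6.

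Gene lists were written from general knowledge before the tests, 22 lists with 450 genes, of which 449 were found. They cover epithelial, mesenchymal, EMT transcription factor, TGF-beta pathway target, collagen and basement membrane, matrix protease, H3K36 methylation enzyme, Polycomb and DNA methylation, proliferation, p53 target, interferon-stimulated, MHC class I presentation, chemokine and cytokine, cholesterol synthesis, hypoxia and glycolysis, classical pancreatic cancer, basal and squamous, MAPK and AP-1 genes, and markers of immune, endothelial, fibroblast and acinar cells. Other lists hold 11 of 28 mesenchymal, 7 of 35 collagen, 5 of 12 fibroblast, 3 of 24 TGF-beta, 2 of 9 EMT factor, 1 of 20 protease and 1 of 24 MAPK genes. Of the marker lists of other cells, 2 of 16 immune, 4 of 10 endothelial, 6 of 12 fibroblast and 1 of 12 acinar genes reached 1 CPM in a wild-type line. Lists were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, with a correlation estimated from the data as an alternative. The fry test was run beside it; its directional p asks whether a list's genes move on balance one way and its mixed p whether they change in either direction, and neither compares them with other genes. In simulated data with 1 shifted list, camera also called 1 unshifted list of the others for the Kdm2a-labelled clones of 6694c2 and 2 for Tgf-b over both lines.

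The changes of Kdm2a-labelled clones and of Tgf-b in a line share wild-type libraries, so 50 simulated data sets without change gave the r and covariance that sharing alone produces. Alternatives were other size factors (relative log expression), no gene filter or a filter of 1 CPM, DESeq2 1.42.0, all 28 libraries in 1 fit, each clone alone, libraries as replicates, and leaving out each library, clone or line in turn. Added after the data were seen were fits without Rn45s and Lars2 and fits with the trend of each library with gene length and GC content removed. For this, GC content was found for 97.9% of genes.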

Results

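RNA-seq counts per gene were analysed for 28 libraries of cultured mouse pancreatic cancer cells. The labels place them in 14 groups of 2 libraries. Clonal lines 6694c2 and 6419c5 each have wild-type cells, 2 clones labelled with a guide against Kdm2a, and wild-type cells given Tgf-b, a cytokine that drives epithelial cells towards a mesenchymal state. The lines Panc02 and 3077c4 each have wild-type cells and 2 clones labelled with a guide against Nsd2. The Panc02 clones carry Nsd1 in their titles and Nsd2 in their genotype field, so they are called Nsd clones here. Kdm2a is a demethylase and Nsd1 and Nsd2 are methyltransferases of lysine 36 of histone H3. The series title places these groups in a study of epithelial-mesenchymal transition (EMT), in which cells lose junction proteins such as E-cadherin and gain mesenchymal genes. Library totals ran from 8724714 to 22024231 counts. The r of log2 CPM between the 2 libraries of a group ran from 0.959 to 0.996. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Levels in CPM, counts scaled to library size, are given as mean ± SD over libraries, and changes as log2 fold changes with their standard error (SE).

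Targeted genes were examined first. Kdm2a (chromosome 19, 4316144 to 4398721, GRCm38.p6) was at 143 ± 1.89 CPM in wild-type 6694c2 cells (n = 2), 168 ± 12.5 in clone c5 and 92.2 ± 12.7 in clone c6. It was at 168 ± 47.1 in wild-type 6419c5 cells, 163 ± 28.1 in clone c1 and 132 ± 13.8 in clone c21. Neither line passed the test for Kdm2a (log2 change -0.22, SE 0.20, adjusted p = 0.439 in 6694c2 and -0.18, SE 0.20, adjusted p = 0.494 in 6419c5). A gene count does not show whether the coding sequence is intact, so the clones are named by their label throughout. Nsd1 (chromosome 13, 55209782 to 55318325), which no label of these 4 clones names, fell in 3 of them. It was at 91.1 ± 0.0882 CPM in wild-type 6694c2 cells, 79.2 ± 4.70 in c5 and 3.49 ± 0.0234 in c6 (log2 change -4.73, SE 0.40, adjusted p = 1.2e-04). In 6419c5 it went from 79.7 ± 21.7 to 12.5 ± 3.23 CPM in c1 and 18.8 ± 4.59 in c21 (log2 changes -2.67 and -2.08). Nsd2 (chromosome 5, 33820676 to 33897966) fell in all 4 Nsd clones. In Panc02 it went from 252 ± 35.1 CPM to 59.3 ± 1.21 in c1 and 171 ± 19.2 in c4 (log2 changes -2.08 and -0.56, adjusted p = 5.7e-04 and 0.0322). In 3077c4 it went from 163 ± 21.9 to 13.3 ± 0.116 in c1 and 29.5 ± 1.07 in c4 (log2 changes -3.64 and -2.49). Nsd1, the gene in the Panc02 titles, was higher in those clones (log2 change 0.49, SE 0.14, adjusted p = 0.0444), and did not pass in 3077c4 (-0.46, SE 0.17, adjusted p = 0.0759).

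**Figure D1:**
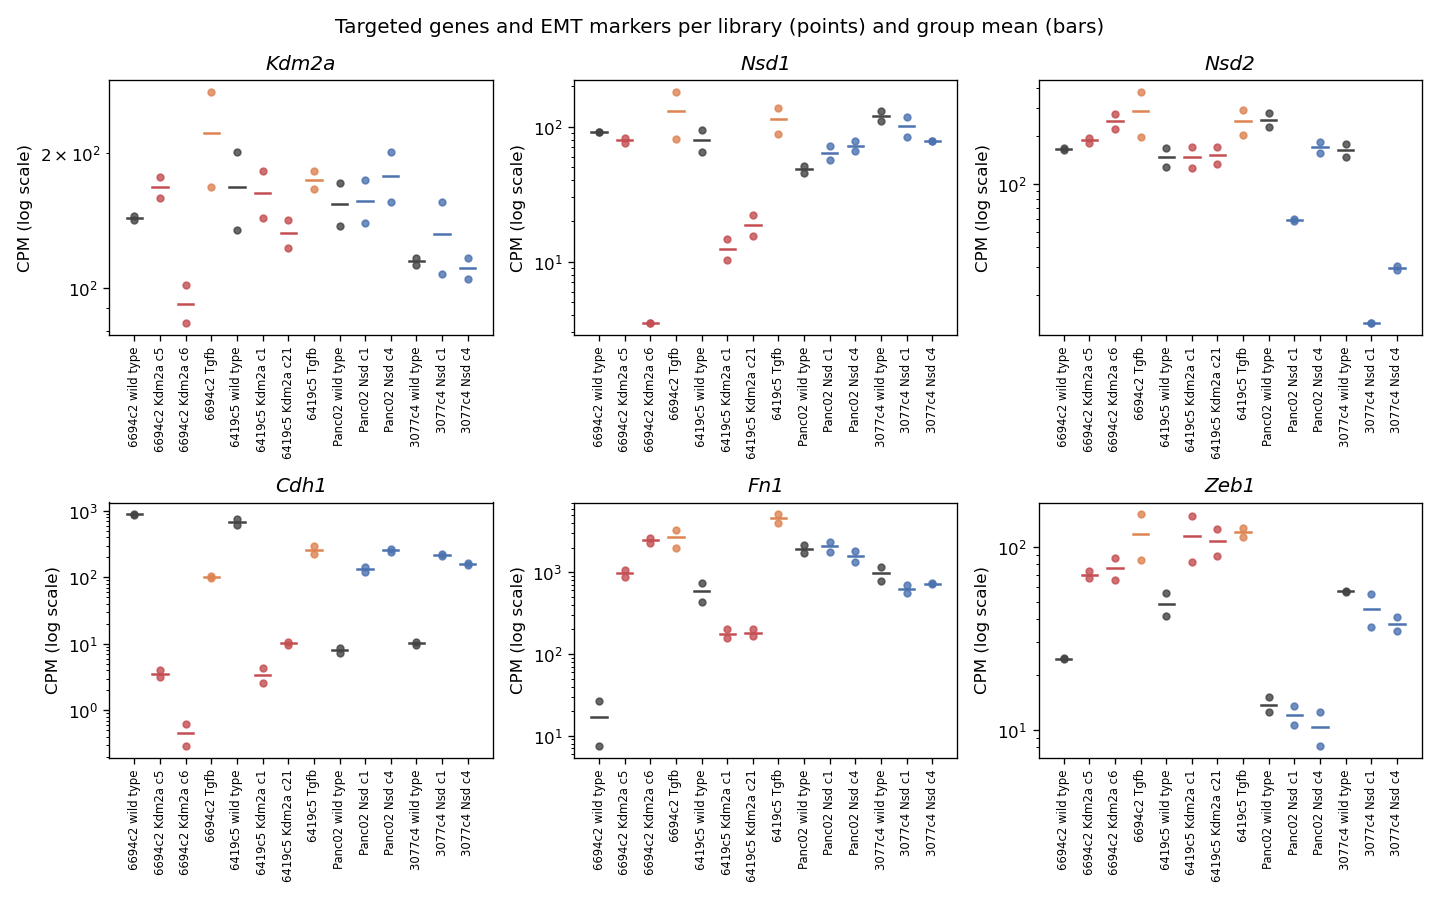
CPM on a log scale of the targeted genes and of Cdh1, Fn1 and Zeb1 in each of the 28 libraries (points), with the group mean as a bar, for the 14 groups on the horizontal axis. Nsd1 is at 3.49 ± 0.0234 CPM in clone c6 of 6694c2 against 91.1 ± 0.0882 in its wild type, while Cdh1 is at 0.453 ± 0.231 against 886 ± 16.5.

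The Kdm2a-labelled clones of 6694c2 had lost most epithelial transcripts. Cdh1 (E-cadherin, the main adhesion protein of epithelial junctions) fell from 886 ± 16.5 CPM (n = 2) to 2.01 ± 1.84 CPM (n = 4), a log2 change of -9.43 (SE 0.21, adjusted p = 8.3e-07). Dsp (desmoplakin, of desmosomes) fell by 10.20 on the log2 scale. Of the epithelial list, 24 of 27 tested genes fell and 0 rose (0 and 24 adjusted over the list alone). The classical pancreatic cancer list, markers of the gland-like tumour subtype, had 15 of 17 genes down and 1 up. Its members Anxa10 and Tff1 had no count in the clones, at least 4079.5-fold lower and at least 848-fold lower than in wild-type cells. Other genes without a count in the clones were Gata5, a transcription factor (at least 1994-fold lower), Eps8l3 (at least 1349-fold lower) and the chloride channel gene Clic6 (at least 1139.7-fold lower). All 7 tested EMT transcription factors rose, among them Zeb2 (6.79 ± 0.50, SE), Prrx1 (5.57 ± 0.34) and Zeb1 (1.57 ± 0.26). Snai1 was 30.6-fold higher (counting interval 5.29 to 1227) than in wild-type cells, where it had 1 count. Fn1 (fibronectin, a matrix protein) rose from 17.1 ± 13.6 CPM (n = 2) to 1723 ± 882 CPM (n = 4), and Thbs1 (thrombospondin 1) by 8.41 ± 0.26. In the collagen and basement membrane list 21 genes rose and 5 fell of 33 tested, and in the mesenchymal list 13 rose and 3 fell of 23. Pdgfrb, the receptor for platelet-derived growth factor on mesenchymal cells, rose by 8.42 ± 0.48, and 5 of 6 tested fibroblast markers rose. Col8a1 was 1059-fold higher (counting interval 293 to 8747), Col3a1 rose by 4.84 ± 0.50, and the collagen receptor Ddr2 had no wild-type count (at least 58.8-fold higher). With genes at 0 set to their bound, the fibroblast median went from 3.79 to 3.42. Nsd2 and Epcam did not pass (adjusted p = 0.287 and 0.154). Vim (vimentin) was at 2816 ± 332 CPM (n = 4) against 2376 ± 93.9 CPM (n = 2) and did not pass (adjusted p = 0.246). The largest rises were in Grem1, a secreted BMP inhibitor (12.02 ± 0.69), and in Mgp (matrix Gla protein), Wisp1 (a secreted Wnt target) and the protocadherin Pcdh18, which had no wild-type count (at least 787-fold higher, at least 598-fold higher and at least 614-fold higher). Among TGF-beta pathway targets 10 rose and 1 fell of 22, led by Ltbp2 (5.05 ± 0.29) and Wnt7b (4.58 ± 0.20). Of 21 cholesterol synthesis genes 20 fell, with Idi1 at -1.52 ± 0.13. In the basal and squamous list 5 of 10 fell, including the keratin Krt14 (-7.69 ± 0.57) and Sprr1a (-6.08 ± 0.34).

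In this comparison 4955 of 12823 tested genes were called by edgeR, 2261 up and 2694 down, and 1298 and 1624 of these changed at least 2-fold. The count was 2441 without wild-type replicate 1, 2595 without wild-type replicate 2, 3299 without c5 replicate 1 and 3303 without c5 replicate 2. With the length and GC trend of each library removed, the calls were 2987 up and 2967 down. Lists were compared with all other genes by camera with a preset correlation (adjusted p = 1.9e-24 for epithelial, 1.7e-21 for classical, 6.3e-07 for EMT transcription factors, 3.2e-04 for mesenchymal, 2.8e-05 for collagen, 8.5e-04 for TGF-beta targets, 1.3e-04 for cholesterol synthesis, 1.5e-04 for fibroblasts and 0.00383 for basal). With an estimated correlation the epithelial and classical calls held (adjusted p = 0.0101 for both), and the others were lost, at adjusted p = 0.0779 with an estimated correlation for the mesenchymal, TGF-beta and collagen lists, 0.0888 for the EMT factors, 0.0968 for fibroblasts, 0.239 for cholesterol synthesis and 0.327 for basal. Longer genes were higher in these clones: the median log2 change was 0.31 in the longest 20% of genes and -0.36 in the shortest. The lists were not retested with this trend removed, so its part in the matrix and EMT factor calls is not known.

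The Kdm2a-labelled clones of 6419c5 had also lost epithelial genes. Cdh1 fell from 681 ± 93.8 CPM (n = 2) to 6.79 ± 3.95 CPM (n = 4) (log2 change -6.81, SE 0.23, adjusted p = 7.2e-07), and Epcam, an epithelial surface protein, from 9.10 ± 1.37 CPM (n = 2) to 1.67 ± 0.731 CPM (n = 4). The junction genes Dsg2 (desmoglein 2), Cdh3 (P-cadherin) and Marveld3 had no count in the clones (at least 1531-fold lower, at least 1105-fold lower and at least 155-fold lower). The epithelial list had 27 genes down and 0 up of 31 tested (0 and 27 adjusted over the list alone). The secretory genes Ctse (cathepsin E, -10.57 ± 0.37) and Muc1 (mucin 1, -5.29 ± 0.16) led the falls of the classical list, in which 10 of 16 fell. Krt14 had no count in the clones (at least 189-fold lower), and Pkp1 (plakophilin 1) fell by 5.12 on the log2 scale, with 5 of 8 basal and squamous genes down. The list's median was -3.44, or -2.65 with genes at 0 set to their bound. Twist2 (4.05 ± 0.26), Twist1 (1.59 ± 0.26) and Zeb1 (1.19 ± 0.27) were among 5 of 8 EMT transcription factors that rose. Fn1 fell from 590.2 ± 222 CPM (n = 2) to 181 ± 22.6 CPM (n = 4). The collagen list had 14 genes down and 6 up of 34, with Col8a1 at -8.53 ± 0.29 and Col3a1 at 6.23 (SE 0.24, adjusted p = 1.0e-06). TGF-beta targets had 12 down and 3 up of 23, with Wnt7b at -7.74 ± 0.30 and the integrin Itgb6 at -7.59 ± 0.42. Cell cycle genes moved up: 19 of 29 rose, with cyclin E1 (Ccne1) at 1.53 ± 0.15 and Mki67 at 1.43 ± 0.47. Of the Polycomb and DNA methylation list 11 rose and 2 fell of 21, led by Cbx7 (2.69 ± 0.24). Of the cholesterol synthesis genes 16 of 21 fell, with Insig1, a sterol sensor, at -2.51 ± 0.16. The forkhead factor Foxf1, the cytochrome Cyp3a16 and the chemokine Cxcl12 had no wild-type count (at least 176-fold higher, at least 171-fold higher and at least 183-fold higher), and Slit3, a guidance cue, was 1497-fold higher (counting interval 268 to 59154). Crisp1 was at least 1418-fold lower and Palmd was at 0.0274 ± 0.0547 CPM (n = 4) against 108 ± 6.97 CPM (n = 2). The laminin chain Lama3 fell from 6.67 ± 2.68 CPM (n = 2) to 0.0315 ± 0.0364 CPM (n = 4). Vim, Snai1 and Nsd2 did not pass (adjusted p = 0.131, 0.121 and 0.927), and the result for Vim depends on how the order of the libraries is treated. With genes at 0 set to their bound, the mesenchymal median went from -0.18 to -0.42 and the fibroblast median from 2.34 to 1.42.

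For 6419c5, edgeR called 5248 of 13094 genes, 2176 up and 3072 down, 950 and 2125 of them by at least 2-fold. With the length and GC trend of each library removed, the share of calls that were up went from 41.5% to 56.1%, and the median of all genes moved by 0.15. Camera gave adjusted p = 1.9e-13 for epithelial, 3.4e-05 for classical, 4.5e-04 for basal, 5.3e-05 for TGF-beta targets, 2.0e-04 for proliferation, 4.5e-04 for cholesterol synthesis, 0.0103 for Polycomb, 0.0118 for collagen and 0.029 for EMT factors. None of these held with an estimated correlation: the adjusted p was then 0.121 for epithelial, basal and TGF-beta targets, 0.143 for classical, 0.152 for proliferation, 0.22 for EMT factors, 0.258 for Polycomb, 0.334 for cholesterol synthesis and 0.558 for collagen.

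Between the lines, the Kdm2a-labelled changes overlapped in the falls more than in the rises. Of genes called in both, 433 rose in both (independent lists would share 361), 1016 fell in both (596 for independent lists), 647 rose in 6694c2 and fell in 6419c5 (508) and 329 the reverse (424), and r across genes was 0.20. Genes are not independent replicates. With each clone summed to 1 value and the line as a covariate, 11 genes were called, 1 up and 10 down. Among the falls were Ctse (-10.87 ± 0.79, adjusted p = 0.0362), Muc1 (-5.64 ± 0.32), the tight junction gene Lsr (-7.37 ± 0.57), Itgb6 (-7.58 ± 0.54), Mal2, of apical transport (-7.51 ± 0.52), Sema4f (-8.24 ± 0.40) and Ncmap (-7.13 ± 0.49). The rise was Itpr2, a calcium release channel (3.22 ± 0.23). Cdh1 did not pass at the level of clones (log2 change -7.81, SE 1.05, adjusted p = 0.0957), nor did Zeb1 (log2 change 1.33, SE 0.19, adjusted p = 0.0959), Nsd1 (log2 change -1.80, SE 1.08, adjusted p = 0.482), Fn1, Epcam, Vim, Snai1, Kdm2a or Nsd2 (lowest adjusted p = 0.354, for Epcam). At this level 0 of 28 epithelial genes rose and 0 fell, while 18 fell adjusted over the list alone. Camera called the epithelial list (median -3.38, adjusted p = 4.9e-23), cholesterol synthesis (-0.96, 2.3e-13), classical (-3.56, 1.8e-09), EMT factors (1.35, 1.7e-05), proliferation (0.23, 1.2e-04), fibroblasts (2.61, 0.00367), Polycomb (0.42, 0.0103), mesenchymal (0.55, 0.0169), hypoxia (-0.61, 0.0169) and basal (-1.57, 0.0174), all of them lost with an estimated correlation (lowest adjusted p = 0.145 with an estimated correlation, for epithelial). The count is small and fragile: it was 0 without clone c5 or c6 of 6694c2 or without c1 of 6419c5, 1 without c21, 87 without the 6694c2 wild type, 475 without the 6419c5 wild type, 52 without a filter, 18 with the CPM filter, 1612 by DESeq2 and 2997 with libraries as replicates. In single simulated data sets with few changed genes, 0% of those changed 4-fold were recovered, and the same share for the interaction. This share need not hold for the real data. The median of all genes moved by 0.16 with the length and GC trend removed. The clone effect differed between the lines for 150 genes by an interaction test (342 without a filter, 2016 by DESeq2, 4410 with libraries as replicates). Zeb2 (6694c2 minus 6419c5 6.17, SE 0.34, adjusted p = 0.0364) rose more in 6694c2, and Wnt7b (12.39, SE 0.90, adjusted p = 0.0375) went in opposite directions, while the difference for Fn1 did not pass (8.22, SE 0.98, adjusted p = 0.062).

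The Nsd clones of Panc02 gained epithelial genes. Cdh1 rose from 7.97 ± 0.975 CPM (n = 2) to 194 ± 72.2 CPM (n = 4) (log2 change 4.54, SE 0.15, adjusted p = 4.3e-05), and Epcam from 1.05 ± 0.435 CPM (n = 2) to 31.5 ± 3.50 CPM (n = 4). The keratin Krt7 rose by 7.07 ± 0.15, and Dsp was 246-fold higher (counting interval 83.9 to 1192) than in wild-type cells. The epithelial list had 25 genes up and 0 down of 30 tested (25 and 0 adjusted over the list alone). Basal and squamous genes rose too, 7 of 9, with Krt14 at 4.65 ± 0.73 and Krt16 74.0-fold higher (counting interval 13.1 to 2942). Snai1, an EMT transcription factor, fell from 56.2 ± 5.42 CPM (n = 2) to 1.47 ± 0.685 CPM (n = 4), and Zeb2 by 1.73 on the log2 scale, while Zeb1 did not pass (log2 change -0.30, SE 0.21, adjusted p = 0.329). In the EMT factor list 1 gene rose and 2 fell of 5. Vim fell from 2054 ± 309.6 CPM (n = 2) to 1218 ± 127 CPM (n = 4), and Fn1 did not pass (log2 change -0.11, SE 0.18, adjusted p = 0.691). In the mesenchymal list 8 genes fell and 2 rose of 21, with the matrix genes Sparc at -6.13 ± 0.47 and Lox at -5.94 ± 0.25, and 4 of 6 fibroblast markers fell and 2 rose, with Pdgfrb at -4.31 ± 0.11. Of the p53 targets 9 rose and 1 fell of 18, led by Perp, which is also a desmosome protein (3.99 ± 0.38), and Plk2 (1.94 ± 0.17). Of the chemokines and cytokines 9 rose and 1 fell of 15, with Csf3 and Ccl20 without a wild-type count (at least 24.3-fold higher and at least 12.01-fold higher). The cadherin Cdh26, Il5ra and Sis also had no wild-type count (at least 454-fold higher, at least 111-fold higher and at least 78.8-fold higher), and Tmtc2 was 558-fold higher (counting interval 99.9 to 22056). Igsf3 and Scara3 had no count in the clones (at least 662-fold lower and at least 329-fold lower), and Mvb12b fell by 9.58 on the log2 scale. The oxidase Fmo2 fell from 53 ± 1.24 CPM (n = 2) to 0.0377 ± 0.0754 CPM (n = 4) and Col3a1 from 2.62 ± 0.645 CPM (n = 2) to 0.0398 ± 0.049 CPM (n = 4). Kdm2a did not pass (adjusted p = 0.616).

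In Panc02, edgeR called 3748 of 11894 genes, 1796 up and 1952 down, 888 and 628 of them by at least 2-fold. The count was 1884 and 2130 without wild-type replicate 1 or 2, and 2314 and 2370 without c1 replicate 1 or 2. It also depends on how the order of the libraries is treated, as do the results for Zeb1 and Kdm2a, which did not pass here. Camera gave adjusted p = 6.9e-39 for epithelial, 6.2e-06 for basal, 9.1e-06 for fibroblasts, 3.4e-04 for mesenchymal and for p53 targets, 0.00186 for chemokines and 0.00625 for EMT factors. The epithelial call held with an estimated correlation (adjusted p = 0.0143), and the others did not (adjusted p = 0.101 with an estimated correlation for basal, fibroblast, mesenchymal and p53 lists, 0.465 for EMT factors and 0.534 for chemokines).

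The Nsd clones of 3077c4 also gained epithelial genes. Cdh1 rose from 10.2 ± 0.723 CPM (n = 2) to 191 ± 35.0 CPM (n = 4) (log2 change 4.18, SE 0.17, adjusted p = 3.9e-06), and the tight junction gene Tjp3 by 4.56 ± 0.23. Epcam, with 3 counts over the 6 libraries, was not detectable at this depth. The epithelial list had 14 up and 0 down of 17 tested (15 and 0 adjusted over the list alone). Hnf4a, a gut and liver transcription factor, rose by 5.16 ± 0.47, with 6 of 12 classical genes up, and the integrin Itgb4 by 4.32 ± 0.32, with 7 of 9 basal genes up. Zeb2 (-1.54 ± 0.16) and Snai2 (-0.97 ± 0.19) were among 4 of 8 EMT factors that fell. Ddr2, a collagen receptor, fell by 3.45 on the log2 scale, with 6 of 23 mesenchymal and 3 of 6 fibroblast genes down. Of the collagen list 14 fell and 4 rose of 32, with Vcan (versican) at -3.67 ± 0.24 and Col8a1 at -3.74 ± 0.34. Hypoxia and glycolysis genes rose, 14 of 18, with Ndrg1 at 4.07 ± 0.19 and Ankrd37 at 2.83 ± 0.29. Of the chemokines and cytokines 11 of 17 rose, with the alarmin Il33 at 3.98 ± 0.18. Antigen presentation genes Tap1 (1.61 ± 0.33) and Psmb9 (2.54 ± 0.55) were among 5 of 12 that rose, and the immediate early genes Fos (2.58 ± 0.34) and Egr1 (1.75 ± 0.21) among 10 of 24. Of 29 proliferation genes 17 fell, including the replication factors Mcm5 (-0.83 ± 0.15) and Mcm2 (-0.82 ± 0.15). Of the histone H3 lysine 36 enzymes 2 of 11 fell, Nsd2 and Ash1l (-0.69 ± 0.15). The acinar list had 1 tested gene, Cela1, which fell (-2.38 ± 0.38). Myh10, a non-muscle myosin, had the largest fall (-8.27 ± 0.30), followed by Stk39, Neto2 and Gphn (-5.07, -5.07 and -4.82). Sprr2a3 and Gabrp had no wild-type count (at least 229.7-fold higher and at least 74.5-fold higher), the homeobox gene Hoxc6 was 487-fold higher (counting interval 87.3 to 19270.0), and Oit1 rose by 6.43 ± 0.51. Ccl7, a monocyte chemokine, was 59.0-fold higher (counting interval 20.03 to 287), the trefoil factor Tff2 32.7-fold higher (counting interval 5.68 to 1309), and Ly6d at least 9.96-fold higher. Pdgfrb fell from 4.01 ± 0.113 CPM (n = 2) to 0.0378 ± 0.0498 CPM (n = 4) and Col1a2 was at -3.18 ± 0.75. Vim, Fn1, Zeb1, Snai1 and Kdm2a did not pass (adjusted p = 0.0985, 0.0538, 0.089, 0.149 and 0.841). The results for Vim, Fn1, Zeb1 and Nsd1 in this line depend on how the order of the libraries is treated.

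In 3077c4, edgeR called 3362 of 12033 genes, 1790 up and 1572 down, 964 and 499 of them by at least 2-fold. With the length and GC trend removed, the balance turned, to 1818 up and 2339 down, and the share of calls that were up went from 53.2% to 43.7%. The count was 1178 and 1379 without wild-type replicate 1 or 2, and 1855 and 1963 without c4 replicate 1 or 2. Clone c1 alone gave 3468 calls and c4 alone 1644. Camera called 14 lists, with adjusted p from 1.3e-21 (epithelial) to 0.0498 (acinar). The epithelial call alone held with an estimated correlation (adjusted p = 0.039); the adjusted p was 0.166 with an estimated correlation for the hypoxia, collagen, EMT factor, classical and basal lists, 0.169 for proliferation, 0.185 for fibroblasts, 0.206 for mesenchymal, 0.238 for chemokines, 0.242 for acinar cells, 0.255 for MAPK, 0.266 for antigen presentation and 0.366 for the histone enzymes. The wild-type library 3077c4 replicate 1 held 14.7% of its counts in Rn45s, the ribosomal RNA precursor, and the longest 20% of genes had a median log2 change of -0.21 in these clones.

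Across both lines with each clone as 1 value, 23 genes were called, 21 up and 2 down. Cdh1 (log2 change 4.40, SE 0.37, adjusted p = 0.045) and the keratin Krt8 (2.29 ± 0.19) rose, as did the protease Ctsh (3.81 ± 0.35), the bacterial sensor Nod2 (3.61 ± 0.36), Fgfbp1 (3.10 ± 0.30), Fcho1 (2.95 ± 0.29), Pdlim1 (2.87 ± 0.27) and the interferon target Bst2 (1.58 ± 0.14). Pdgfrb (-4.85 ± 0.43) and the polarity scaffold Mpdz (-4.47 ± 0.40) fell. Nsd2 (log2 change -2.14, SE 0.60, adjusted p = 0.197), Nsd1, Kdm2a, Epcam, Vim, Fn1, Zeb1 and Snai1 did not pass (lowest adjusted p = 0.196 among them). In the epithelial list 3 of 32 rose, or 19 adjusted over the list alone, and of 18 chemokines 0 rose, or 9 adjusted over the list alone. Camera called epithelial (median 1.81, adjusted p = 1.9e-27), chemokines (1.40, 3.3e-08), proliferation (-0.36, 3.0e-08), hypoxia (0.66, 1.5e-05), antigen presentation (0.58, 2.7e-04), immune cell markers (1.68, 0.00462), interferon-stimulated genes (0.56, 0.0368), classical (1.22, 4.0e-05), basal (1.70, 2.3e-04), fibroblasts (-1.47, 2.4e-04), mesenchymal (-0.23, 4.6e-04), EMT factors (-0.49, 0.00286), p53 targets (0.31, 0.00563), MAPK (0.19, 0.00563) and Polycomb (-0.19, 0.0292), and none held with an estimated correlation (lowest adjusted p = 0.134 with an estimated correlation). The count was 0 without any 1 of the 4 clones, 1250 without the Panc02 wild type, 1542 without the 3077c4 wild type, 0 with the length and GC trend removed, 1202 by DESeq2 and 2016 with libraries as replicates. The lines differed in the clone effect for 1126 genes (498 without a filter, 2029 by DESeq2, 3181 with libraries as replicates). In simulated data of these shapes, unchanged genes made up 12.3% of the calls by clone and 21.4% of those for the interaction, above the nominal 5%. Those data were single sets with few changed genes, so these shares are not those of the real calls. Snai1 (Panc02 minus 3077c4 -4.78, SE 0.58, adjusted p = 0.0101) and Sparc (-6.04, SE 0.24, adjusted p = 6.7e-04) fell in Panc02 and did not pass in 3077c4, Il33 (-9.13, SE 0.50, adjusted p = 0.00116) fell in Panc02 and rose in 3077c4, and the difference for Cdh1 did not pass (0.37, SE 0.56, adjusted p = 0.711). Of genes called in both lines, 372 rose in both (211 for independent lists) and 256 fell in both (239). Another 235 rose in Panc02 and fell in 3077c4 (190), and 329 did the reverse (265). Across genes r was 0.112 but rho 0.003, and 49.4% of genes had the same sign in both lines. Against the Kdm2a-labelled clones, by clone, r across genes was -0.27 and rho -0.33.

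Epithelial genes were lower and matrix genes higher in the Tgf-b libraries of both lines. By their library numbers these libraries lie outside the sets that hold their wild-type controls, so treatment and library set coincide. Treated 6419c5 cells also had chromosomes 2 and 16 at median log2 changes of 0.36 and 0.48. The changes below are therefore differences between these groups of libraries. Cdh1 fell from 886 ± 16.5 CPM (n = 2) to 101.3 ± 3.92 CPM (n = 2) in 6694c2 (log2 change -3.13, SE 0.20, adjusted p = 5.9e-05) and from 681 ± 93.8 CPM (n = 2) to 258 ± 49.7 CPM (n = 2) in 6419c5 (-1.37, SE 0.24, adjusted p = 0.00384). Fn1 rose from 17.1 ± 13.6 CPM (n = 2) to 2680.3 ± 946 CPM (n = 2) in 6694c2 and from 590.2 ± 222 CPM (n = 2) to 4581 ± 834 CPM (n = 2) in 6419c5. Over both lines 22 epithelial genes fell and 2 rose of 30, with Tjp3 at -4.87 ± 0.63, and Prss8, a serine protease, without a count after treatment (at least 19.4-fold lower). The TGF-beta pathway targets had 19 up and 2 down of 23, led by Ltbp2 (6.67 ± 0.23). Of the collagen list 21 rose and 3 fell of 33, with Col12a1 at 7.88 ± 0.61 and Col7a1 at 7.56 ± 0.47, and of the mesenchymal list 17 rose and 2 fell of 24, with Tnc (tenascin C) at 6.49 ± 0.79. Snai1 (5.01 ± 0.70), Zeb2 (4.48 ± 0.78) and Zeb1 (1.79 ± 0.27) were among 5 of 8 EMT factors that rose. Among matrix proteases 11 rose and 1 fell of 18, with Mmp9 at 8.10 ± 0.42 and Mmp10 at 5.81 ± 0.62. Of the fibroblast markers 5 of 6 rose, with Pdgfrb at 6.96 ± 0.68 and Col1a1 at 5.50 ± 0.32. The classical list had 11 down and 1 up of 15, with Tspan8 at -4.54 ± 0.21, and cholesterol synthesis 17 down of 21, with Pmvk at -2.07 ± 0.30 and Mvd at -1.92 ± 0.19. The AP-1 gene Fosb rose (3.98 ± 0.41), with 9 up and 5 down of 24 in its list. The largest rises were Il11, a cytokine of the IL-6 family (11.19 ± 0.48), Has2, which makes hyaluronan (9.76 ± 0.64), Fam167a (8.86 ± 0.46), Col5a3 (1153-fold higher (counting interval 394 to 5595)), the transcription factor Runx3 (1079-fold higher (counting interval 193 to 42664)), and Lrrc32, which holds latent TGF-beta at the cell surface (829-fold higher (counting interval 283 to 4021)). Sptssb, Tmigd1, the gap junction gene Gjb1, Slurp1 and the nuclear receptor Nr0b2 had no count after treatment (at least 999-fold lower, at least 890.3-fold lower, at least 765-fold lower, at least 531-fold lower and at least 288-fold lower). In the 6694c2 comparison, Wisp1 and Adamts7, a matrix protease, had no wild-type count (at least 1607-fold higher and at least 236-fold higher), as had Ddr2 (at least 15.7-fold higher) and the early growth response gene Egr2 (at least 12.8-fold higher), and Snai1 was 196-fold higher (counting interval 34.8 to 7764). Wnt7b (7.13 ± 0.22) and Adam12 (7.96 ± 0.47) rose there, Marveld3 fell by 4.79 on the log2 scale, and Ugt2b34, Tff2 and the galectin Lgals4 had no count after treatment (at least 2381-fold lower, at least 438-fold lower and at least 65.1-fold lower). In the 6419c5 comparison, Nectin1, an adhesion protein, was 1994-fold higher (counting interval 358 to 78813), Fcgbp, Postn (periostin) and Col1a2 had no wild-type count (at least 123-fold higher, at least 31.6-fold higher and at least 44.1-fold higher), and Adam12 rose by 4.76 ± 0.28. Krt19 fell there (-5.69 ± 0.38), Crisp1 was at least 909-fold lower, Ddc fell from 139.8 ± 1.61 CPM (n = 2) to 0.0248 ± 0.0351 CPM (n = 2), and Lgals4 from 7.65 ± 0.157 CPM (n = 2) to 0.0248 ± 0.0351 CPM (n = 2). The fibroblast median in 6694c2 went from 3.36 to 1.65 with genes at 0 set to their bound, and the interferon median from -0.14 to -0.05. Kdm2a and Epcam did not pass over both lines (adjusted p = 0.23 and 0.497). Vim did not pass in either line (adjusted p = 0.952 and 0.0593).

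For Tgf-b, edgeR called 5090 genes in 6694c2 (2677 up, 2413 down), 3651 in 6419c5 (1861 up, 1790 down) and 4793 over both lines (2488 up, 2305 down). The fit over both lines took single libraries as replicates. Its count therefore cannot be set against the counts by clone over both lines (11 and 23), which rose with libraries as replicates. In 6694c2 the count was 8412 without Tgfb replicate 2, 2113 without wild-type replicate 1 and 2373 without wild-type replicate 2; in 6419c5 it was 1833 without wild-type replicate 1 and 2177 without Tgfb replicate 2. Over both lines it was 3107 and 3084 without the 6694c2 wild-type replicate 1 or 2 and 3169 without the 6419c5 wild-type replicate 1. At least 2-fold changes numbered 1446 up and 1368 down over both lines. Within single lines, camera also called interferon-stimulated genes in 6419c5, where 7 fell and 1 rose of 21, with Rtp4 at -5.31 ± 1.02 and Oas2 at least 3.20-fold lower (adjusted p = 0.0245, or 0.272 with an estimated correlation). Over both lines camera gave adjusted p = 2.4e-13 for TGF-beta targets, 6.6e-11 for mesenchymal, 8.0e-11 for classical, 5.5e-10 for collagen, 7.1e-09 for epithelial and 1.5e-08 for cholesterol synthesis, and these 6 held with an estimated correlation (adjusted p = 0.00852 to 0.0436). The fibroblast, matrix protease, EMT factor and MAPK calls did not (adjusted p = 0.116, 0.0905, 0.285 and 0.499 with an estimated correlation). Within each line the TGF-beta target, collagen, mesenchymal, classical and epithelial calls held as well, and in 6419c5 the fibroblast call (adjusted p = 0.0196), while cholesterol synthesis was lost (adjusted p = 0.18 in 6694c2 and 0.151 in 6419c5 with an estimated correlation), as were the protease (0.0644 and 0.0593) and EMT factor lists (0.267 and 0.0988), and in 6694c2 the fibroblast (0.186) and MAPK lists (0.175). Long genes were higher in treated cells, with a median log2 change of 0.53 in the longest 20% and -0.50 in the shortest. The lists were not retested with this trend removed, so its part in the collagen and matrix calls is not known. With the trend removed, calls in 6694c2 were 2743 up and 2770 down, and over both lines Nsd1 turned from 0.54 to -0.50 and Nsd2 from 0.79 to -0.26. The 2 lines shared 1276 rises (373 for independent lists) and 1118 falls (310), with 53 genes opposite and r = 0.753 across genes. The effect differed between lines for 400 genes (758 without a filter, 916 by DESeq2, 984 with the length and GC trend removed, 74 without the 6694c2 wild-type replicate 1, 911 without its Tgfb replicate 2, and 106 to 144 without any of the other wild-type libraries or the 6419c5 Tgfb libraries). The share of these that were higher in 6694c2 went from 65.2% to 52.9% with the length and GC trend removed, and the median of all genes moved by -0.11. Cdh1 (6694c2 minus 6419c5 -1.70, SE 0.29, adjusted p = 0.0239) fell more and Fn1 (4.36, SE 0.83, adjusted p = 0.0373) and Zeb2 (3.93, SE 0.65, adjusted p = 0.0218) rose more in 6694c2. The characteristics give treatments of 4, 5, 6 and 7 days for these 4 libraries and the protocol gives 4 days at 10 ng/mL for all, so time was not fitted.

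**Figure D2:**
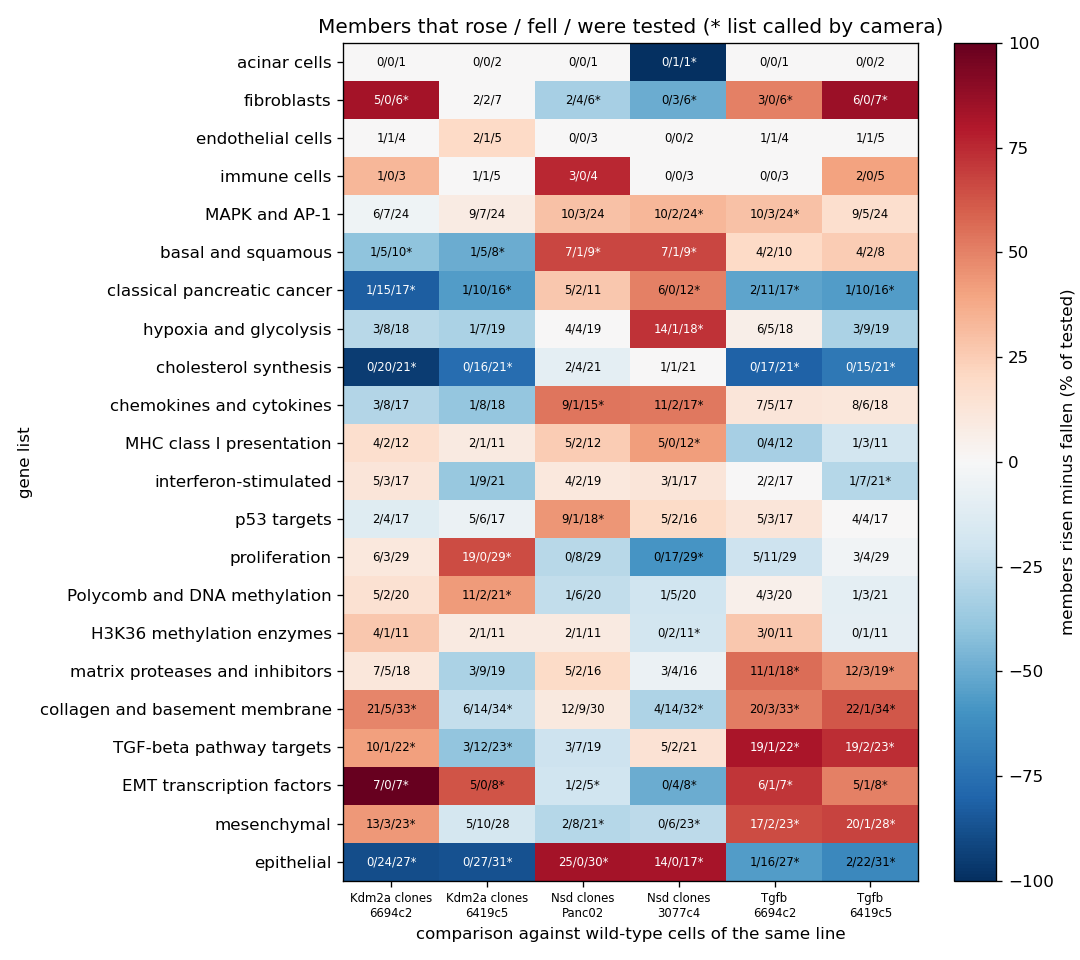
Gene lists (vertical axis) against the 6 comparisons with wild-type cells of the same line (horizontal axis), coloured by members risen minus fallen as a percentage of those tested, with the counts that rose, fell and were tested in each cell and an asterisk where camera called the list. The epithelial list is 0/24/27 in the Kdm2a-labelled clones of 6694c2 and 25/0/30 in the Nsd clones of Panc02.

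The Kdm2a-labelled and Tgf-b changes were set side by side within each line. Both are measured against the same wild-type libraries, so chance values are shared. In 6694c2, r across genes was 0.599, against 0.581 for simulated groups without change, while the covariance was 2.69 against 0.203; 1352 genes rose in both and 1421 fell in both (472 and 507 for independent lists). Fn1, Zeb2, Ltbp2 and Wnt7b rose and Cdh1 fell under both. In 6419c5, r was 0.160 against 0.581 simulated, and the covariance 0.490 against 0.127; 436 genes rose in both and 878 fell in both (309 and 420 for independent lists), while 213 rose in the clones and fell after Tgf-b (297) and 488 did the reverse (437). There Fn1, Wnt7b and Col8a1 were among the genes set apart, with Fn1 at -1.69 in the clones and 2.98 after Tgf-b, while Cdh1 fell under both. The controls have 2 libraries, so each part of a split would hold 1, and no split was made. The simulated covariance covers sharing only at the spread between these libraries. Part of the excess may therefore still come from the shared controls. The counts for independent lists make no allowance for them either. In 6419c5, chromosomes 2 and 16 had raised medians against this wild type in both clones (0.44 and 0.34) and after Tgf-b (0.36 and 0.48). The simulation holds no such shift, so the genes that rose in both may include some of these chromosomes for that reason.

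Wild-type Panc02 and 3077c4 cells were compared with wild-type 6694c2 and 6419c5 cells, 1 sum per line. Cdh1 was at 9.09 ± 1.47 CPM (n = 4) against 784 ± 131 CPM (n = 4) and Snai1 at 38.2 ± 21.7 CPM (n = 4) against 0.242 ± 0.281 CPM (n = 4), and neither passed. Nor did Fn1, Zeb1, Vim, Epcam, Kdm2a, Nsd1 or Nsd2 (lowest adjusted p = 0.624 among them). For Cdh1 the test gave a log2 change -6.43, SE 0.38, adjusted p = 0.0714, and for Snai1 a log2 change 7.23, SE 1.52, adjusted p = 0.262. edgeR called 0 of 12772 genes, with 1467 at an unadjusted p under 0.05, and DESeq2 called 946. Without the 3077c4 wild type, edgeR called 110 genes. In a single simulated data set with few changed genes, 0% of those changed 4-fold were recovered, a share that need not hold for the real data. With the length and GC trend removed the median of all genes moved by 0.25. Camera called the epithelial (median -2.42, adjusted p = 4.3e-19) and classical lists (-4.85, 1.7e-14) as lower and proliferation (0.45, 1.2e-04), fibroblasts (2.91, 0.00385), EMT factors (2.29, 0.048) and Polycomb genes (0.55, 0.048) as higher. The basal list was lower (-1.18, 0.048). None held (lowest adjusted p = 0.297 with an estimated correlation).

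Clones of the same line and label were compared with each other. In 6694c2, clone c6 had less Nsd1 than c5 (log2 difference -4.52, SE 0.40, adjusted p = 4.6e-04), less Cdh1 (-2.95, SE 0.31, adjusted p = 9.2e-04) and less Kdm2a (-0.89, SE 0.24, adjusted p = 0.0401; genes of chromosome 19, which carries Kdm2a, had a median log2 difference of -0.80), while Fn1 did not pass (1.32, SE 0.52, adjusted p = 0.119) nor did Zeb1 (0.10, adjusted p = 0.841). Clone c4 of Panc02 had more Nsd2 than c1 (log2 difference 1.52, SE 0.14, adjusted p = 0.0288), as had c4 of 3077c4 than its c1 (1.15, SE 0.17, adjusted p = 0.0317). These genes belong to the fixed panel of targeted and EMT genes. edgeR called 2486 genes between the 6694c2 clones, 997 higher in c6 and 1489 lower, 46 between the 6419c5 clones, 27 between the Panc02 clones and 81 between the 3077c4 clones. These counts change with the filter, the tool, the trend correction and how the order of the libraries is treated, so they do not rank the pairs. With the length and GC trend removed, the share of the 6694c2 calls that were higher in c6 went from 40.1% to 53.8%. Among the marker lists of other cell types, endothelial markers were called in none of the comparisons by camera, with 2 up and 1 down of 5 tested in the Kdm2a-labelled clones of 6419c5.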

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

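The interaction tests were planned; which of the named genes to describe here followed from their result. The log2 differences below are effects in the first-named line minus those in the other, and for genes at or near 0 counts they depend on the prior count and are no bound.

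The Kdm2a-labelled clones changed 150 genes differently in 6694c2 and 6419c5. Wisp1 (6694c2 minus 6419c5 21.96), Wnt7b (12.39) and Grem1 (10.74), which encode secreted Wnt or BMP pathway proteins, were higher in the 6694c2 clones relative to their wild type than in the 6419c5 clones; Wisp1 and Wnt7b fell in 6419c5 (-8.87 and -7.74). The EMT factor Zeb2 rose by 6.79 in 6694c2 and 0.59 in 6419c5 (difference 6.17), and Eps8l3, of the actin cytoskeleton, fell only in 6694c2 (difference -14.13).

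The Nsd clones changed 1126 genes differently in Panc02 and 3077c4. In a single simulated data set with few changed genes, 21.4% of calls were unchanged genes, a share that need not hold for the real calls. Panc02 gained more of the epithelial and keratin genes Epcam (Panc02 minus 3077c4 6.71), Dsp (7.99), Krt14 (6.98), Krt7 (4.58) and Perp (3.28), of which Epcam, Dsp and Krt14 were too low for a test in 3077c4 alone. Snai1 (-4.78), Sparc (-6.04), Igsf3 (-12.21) and Vim (-1.28) fell in Panc02 and did not pass in 3077c4, Mvb12b (-9.15) fell in Panc02 and rose in 3077c4, and Mpdz (-1.75) fell in both, more in Panc02. Genes that fell in 3077c4 and not in Panc02 were Myh10 (8.17), Neto2 (9.55, too low for a test in Panc02 alone), Ddr2 (3.13), Mcm5 (0.95) and Cela1 (3.89), while Col8a1 fell in 3077c4 and rose in Panc02 (5.73). Genes that rose in 3077c4 were lower in the contrast: Ndrg1 (-4.04) and Ankrd37 (-2.28) of the hypoxia list, Itgb4 (-2.54), Hoxc6 (-8.86), and Il33 (-9.13) and Egr1 (-3.01), which fell in Panc02. Plk2 (2.10) rose only in Panc02.

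Tgf-b changed 400 genes differently in 6694c2 and 6419c5. Cdh1 fell by 3.13 and 1.37 on the log2 scale (6694c2 minus 6419c5 -1.70). Matrix and signalling genes rose more in 6694c2: Fn1 (4.36), Has2 (6.44), Wisp1 (9.31), Adamts7 (8.99), Wnt7b (3.89), Col7a1 (2.06), Adam12 (3.25), Fosb (1.89) and the EMT factor Zeb2 (3.93). Nectin1 rose more in 6419c5 (-8.44), and Crisp1 (10.73) fell more there. The number of calls with the Tgf-b label over both lines, 4793, was reached by 1 of 34 splits of these 8 libraries, the real one. The highest other split gave 1. Every other split mixed treated and untreated libraries, which puts the difference between them into the spread. Low counts there were therefore built in, and the splits show only that the 2 groups differ.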

How the results depend on the processing

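The fits without Rn45s and Lars2, with the length and GC trend removed and with a replicate block were chosen only after the data were seen. The labels give no replicate numbers, so the block took the order of library numbers, which run through the wild-type and clone libraries in 2 sets; the Tgf-b libraries lie outside these sets, and sums by clone hold both libraries. The r of deviations between groups of a line was 0.47 to 0.72 in Panc02, 0.61 to 0.65 in 6419c5 and 0.23 to 0.31 in 3077c4, but -0.35 to 0.15 in 6694c2, a hint from the data and not from the design. With the block, calls against wild type were 3996 for 6694c2, 6666 for 6419c5, 7695 for Panc02 and 4625 for 3077c4, and calls between clones 1514, 77, 1616 and 566, so the 6694c2 pair no longer had the most. Genes called for the Kdm2a-labelled clones by clone (11) became 52 without a filter, 18 with the CPM filter, 1612 by DESeq2, 2997 with libraries as replicates and 0 to 475 with a clone or wild type left out. For the Nsd clones by clone (23) they became 1202 by DESeq2, 2016 with libraries as replicates, 0 with the trend removed and 0 to 1542 on leaving out. Leaving out 1 library gave 2441 to 4167 for the Kdm2a-labelled clones of 6694c2 (4955), 1884 to 3024 for the Nsd clones of Panc02 (3748), 1178 to 5014 for those of 3077c4 (3362; 1644 with clone c4 alone), and 2113 to 8412, 1833 to 3430 and 3084 to 5058 for Tgf-b in 6694c2, 6419c5 and both. The wild-type comparison (0) gave 18 without a filter, 946 by DESeq2, 2 with the trend removed and 0 to 110 on leaving out. Interactions gave 342 without a filter, 2016 by DESeq2 and 4410 with libraries as replicates for Kdm2a-labelled clones (150); 498, 2029 and 3181 for Nsd clones (1126); and 758 without a filter, 916 by DESeq2, 984 with the trend removed and 74 to 911 on leaving out for Tgf-b (400). Between clones, the trend removed gave 4041 for 6694c2 (2486); no filter, DESeq2, trend removed and all 28 libraries gave 226, 148, 100 and 83 for 6419c5 (46), 130, 146, 69 and 65 for Panc02 (27) and 563, 376, 271 and 412 for 3077c4 (81). Of the list calls, 21 held and 80 were lost with an estimated correlation. The fry test left 171 of 220 list results the same, 16 weaker and 33 stronger. The r of Kdm2a-labelled and Tgf-b changes in 6419c5 was 0.0249 among genes of high expression. With the trend removed, the Tgf-b changes of Nsd1 and Nsd2 reversed, to -0.64 and -0.36 in 6694c2 and to -0.50 and -0.26 over both lines. Calls on named genes stayed the same for 273 of 288 by DESeq2, 267 of 288 with the trend removed, 1507 of 1649 on leaving out, and 129 of 136 with the replicate block, where 7 gained a call: Vim in 6419c5 (0.35) and 3077c4 (0.50), Kdm2a (0.12) and Zeb1 (-0.31) in Panc02, and Nsd1 (-0.47), Fn1 (-0.54) and Zeb1 (-0.49) in 3077c4.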

Other observations

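The tests of low Nsd1 by a mesenchymal state, a swap or a guide, and the count on other chromosomes, were chosen only after the result was seen. Medians of whole chromosomes also shifted; those beyond 0.3 on the log2 scale against wild type are given here. In 6694c2, clone c5 had chromosome 6 at -0.41, 16 at -0.51 and X at 0.62, and clone c6 had 1 at 0.34, 6 at -0.37, 16 at -0.34 and 19, which carries Kdm2a, at -0.88. In 6419c5, clones c1 and c21 had 2 at 0.44 in both, 7 at 0.31 and 0.37, 16 at 0.34 in both and 19 at -0.51 and -0.59, and c21 had 5 at -0.36; Tgf-b cells had 2 at 0.36 and 16 at 0.48 against the same wild type, so these 2 shifts are not particular to the clones. In Panc02, clones c1 and c4 had 2 at -0.47 and -0.44, 16 at -0.34 and -0.32 and X at -0.52 in both, and c4 had 12 at -0.38; both share 1 wild type. In 3077c4, clone c1 had 18 at -0.30.

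Nsd1 was low in 3 of 4 clones labelled Kdm2a. Loss of the surrounding chromosome could lower it, but expressed genes within 500 kb had a median log2 change of -0.0034. A mesenchymal state could lower it, and this stays open: clone c5 lost Cdh1 with Nsd1 at -0.20 (SE 0.33), while after Tgf-b the smaller change of Nsd1, 0.52, did not pass, nor did the other, and with the length and GC trend removed it turned to -0.64. A swap with Panc02 libraries was tested, and all 6 libraries correlated better with another group labelled as their line than with any Panc02 group. For clone c6 of 6694c2 that group was c5 (r 0.927 and 0.932). The 6419c5 clones c1 and c21 were closest to each other (r 0.983 to 0.987), as they would be if swapped together. For these 2 clones the match decides nothing. Wild-type Panc02 libraries were closest to Panc02 clone c1 (r 0.950), which a swap of both Panc02 clones would not give. A guide or background that targets Nsd1 is a candidate explanation that stays open: of the labels of these libraries, 0 name Nsd1.

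In the planned fits, more genes differed between the Kdm2a-labelled clones of 6694c2 than between any other pair. Genes on chromosomes 7, 19 and X, whose medians differed by more than 0.3, do not make up the whole excess in these fits. Outside them lay 1855 calls, against 81 calls in all for the next pair. Chromosomes with smaller shifts, such as 15 at -0.20, count as outside, and gain or loss of part of a chromosome was not tested. For the calls on chromosomes 7, 19 and X, which hold 14.4% of genes, gain or loss could add calls and stays open. Their share, 23.8% (SE 0.86, with genes taken as independent), was within 2 SE of the 25% set beforehand as the bound. Trends with length and GC content do not account for the excess, since 4041 genes were called with them removed. Lower spread alone would not give larger differences, and the median absolute log2 difference was 1.81 times that of the next pair. The number of calls, however, also depends on the spread. With the replicate block, the 6694c2 pair no longer had the most calls. Spread that the planned fits leave in the other lines therefore stays open as a source of the excess in calls.

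Long genes were higher in Tgf-b libraries. A length and GC trend of the libraries could produce calls, and the count does not settle it: with the trend removed it was 100.8% of the count with it, but only 3628 of the 4793 calls were shared. Ribosomal RNA content could move with it, but the slope was 0.21 log2 per doubling of length or more in the treated libraries with under 1% Rn45s. A response of long genes to Tgf-b and a library trend that moves with the treatment cannot be told apart here.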
